A study of Ovis aries with 6 samples.

How the data were processed

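RNA of 3 samples of skin epidermal stem cells and 3 of corneal epithelial cells from sheep, called cell lines in the series' design text, was labelled with Cy3 and hybridised to Agilent sheep expression arrays, 1 array per sample, per the labels' protocols. Spot intensities were extracted with Agilent Feature Extraction 10.7, per the submitters' processing notes. The deposited scanner values are linear intensities, and per the file headers the processed signal had its background subtracted and was detrended within the array, with surrogate values for dim spots. No scaling between arrays is recorded in the headers. The authors also deposited a table of log2 values for the same arrays, whose processing is not given in the sources used here. Each of its 6 columns had a median of 7.23 over 15008 probes, and its correlation with the log2 processed signal of its own array rounded to 0.999 or 1.00. Values of equal rank differed by at most 0.020 between columns over its 15066 probes and control features, as quantile normalization leaves them. By these comparisons the values are log2 and quantile normalized, genes are not centred, and single-colour values have no direction, so none of the 3 stays unknown. They served as an alternative.

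Groups and replicate numbers were taken from the labels. The arrays held 15208 gene spots, 459 positive and 77 negative control spots, and control spots were left out. Spots that the scanner software marked as non-uniform or population outliers were left out, which removed values of 19 probes. The log2 of the processed signal minus each array's 75th percentile was averaged over the spots of a probe. Of 15008 probes, 11742 that were well above background on at least 3 of the 6 arrays, whatever their group, were kept. A gene was represented by its kept probe with the highest mean value, and probes without a gene name were tested as transcripts of their own. Of 516 genes with several kept probes, 342 were called, and in 25 of these the probes differed in the sign of the change.

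Gene names came from the arrays' own annotation columns, matched to a table of sheep RefSeq genes of the assembly ARS-UI_Ramb_v3.0, used for names alone. Of the probes, 786 carried a RefSeq accession and 743 of these matched. Another 552 matched by current symbol, 22 by synonym, 254 by an older gene name and 1251 by a protein description, and 12186 stayed without a name. The 2822 probes with a symbol covered 2004 symbols. KRT12, KRT3, KRT10, ITGA6, CDH1 and MKI67, which were to be named, had no probe named so and were not analysed here.

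Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), corneal minus epidermal, over all 6 arrays with no block, and adjusted by Benjamini-Hochberg, with a threshold of 0.05 and, for counts by size, a fitted change of at least 1 on the log2 scale. A probe not well above background on any array of a group has only a bound there. Its change is given as at least N-fold, the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. No fold is given where the bound is under 1. An adjusted p printed beside a bound tests the fitted change and not the bound. Array quality was compared with an exact permutation test, which cannot give p under 0.1 with 3 against 3.

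For gene groups, 38 lists were fixed before the data were examined, and 28 with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation was run beside it, under which no list passed. That variant rests on the few residual degrees of freedom of 6 arrays, so its failures do not by themselves argue against a call. fry, which tests whether a list's genes move on balance one way and does not compare them with other genes, was a second test. The lists cover corneal epithelium, eye field factors, limbal progenitors, basal and follicle stem cells, epidermal differentiation, wound-activated and hair keratins, simple epithelia, junctions, mesenchymal cells, HOX genes, corneal stroma, corneal endothelium, melanocytes, endothelium, immune cells, smooth muscle, neural crest, skeletal muscle, adipocytes, pluripotency, cell cycle, its inhibitors, Wnt, Notch, TGF-beta and BMP, growth factors, basement membrane, proteases, interferon response, inflammation, antioxidants, glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, protein folding, immediate early genes and retinoid signalling. Counts adjusted over the list alone equalled those over all genes unless both are given.

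Named genes followed a rule fixed at the same time: the 12 largest fitted rises and 12 largest fitted falls with a symbol among called genes, up to 3 called members of each list in each direction, a fixed set of epithelial, stem cell and mesenchymal markers, and the 2 members of highest level of each list of another cell type. This gave 167 genes, a selection of which is printed, and some of which are not reported here.

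Alternatives covered normexp background correction (offset 50), quantile normalization, median centring, no scaling, the deposited log2 table, other filters on dim or marked spots, the mean of a gene's probes, a trend and robust variance, array weights, the replicate number as a block, each array left out in turn, a threshold of 0.01, limma's treat, and the other list tests. Another 3 were chosen after seeing the data: marked spots kept, names from descriptions or older names not used, and normexp without spots whose local background exceeded 10 times the array's median.

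The procedure was tested on simulated data for this comparison, with 11097 genes in the fit and 50 simulated genes per fold. It found 52% of genes changed by 1.25-fold, 64% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, called 0.0551% of 10884 unchanged genes, and 3.61% of its calls were false. A simulated list of 13 genes shifted by 0.5 on the log2 scale was called and 0 other lists were. The simulated noise was independent between genes and few genes changed. In the real data 59.3% of those tested were called, and the estimated correlation of the same list was 0.17. The simulated rates therefore need not hold there. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and the R packages data.table (version 1.17.8) and statmod 1.5.0, were used for tables and figures.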

Results

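Gene expression was measured in cultured sheep (Ovis aries) cells of 2 kinds, skin epidermal stem cells and corneal epithelial cells. By their names, the former are progenitors of the keratinocytes of skin, and the latter come from the epithelium at the surface of the eye. Each kind was represented by 3 samples, which the series' design text calls cell lines, with 1 single-colour (Cy3) array each, so the number of arrays limits the precision of every value. Of the 15208 gene spots on an array, 12414, 11785 and 12401 were well above background in epidermal replicates 1, 2 and 3, and 11539, 11091 and 11176 in corneal replicates 1, 2 and 3. The share of such spots was 80.2% ± 2.36 (SD, n = 3) in the epidermal and 74.1% ± 1.56 (SD, n = 3) in the corneal arrays, with an exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give. No spot was saturated. All 6 arrays lay on 1 slide in 1 scan, the epidermal arrays in slide row 1 and the corneal arrays in slide row 2, so slide row and cell type cannot be told apart.

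Arrays of one group were close to each other. Correlations across probes, which are not independent replicates, ran from 0.992 to 0.993 within groups and from 0.975 to 0.979 between them. Between 54 and 72 genes were over 2-fold apart in a pair of epidermal arrays and 156 to 196 in a pair of corneal arrays, against 920 to 994 across groups. The median SD of a spot between the 3 arrays of a group was 0.05 (log2) in the epidermal and 0.06 in the corneal arrays, among 22 probes printed 5 times and well above background on all 6 arrays. The 5 spots of such a probe on a single array had a median SD of 0.08. For these probes the replicate arrays therefore differed no more than the spots of a single array, and p-values measure only the spread between these samples, which may be technical.

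The single comparison asks which transcripts differ between the corneal and the epidermal cells. In corneal cells, 8 of 13 measured cell cycle genes were higher and 1 was lower, and all 6 measured HOX genes were lower. Both lists passed camera with its preset correlation (adjusted p = 0.0178 each) but not with an estimated correlation (adjusted p = 0.808 and 0.737). With 6 arrays the latter variant has little power. Of 22 mesenchymal markers, 12 were lower and 5 higher, and the list did not pass camera (adjusted p = 0.181). PTGS1, the constitutive cyclooxygenase, had the largest rise with a symbol among genes measured in both groups, from −4.19 ± 0.03 in epidermal to 1.68 ± 0.02 in corneal cells (normalized log2, mean ± SD, n = 3). The largest such fall was that of SFRP2, a secreted Wnt modulator, which was 72.8-fold lower in corneal cells, and POSTN, a secreted matrix protein at background there, was at least 59.7-fold lower. Keratins of basal keratinocytes were at or near background in both kinds of cells, while VIM and DCN, typical of mesenchymal cells, were bright in both.

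Of 11097 genes and unnamed transcripts tested with limma, 2960 were higher and 3617 lower in corneal cells at an adjusted p under 0.05, and 373 were higher and 437 lower by at least 2-fold. Of these, 15 of the 2-fold rises and 136 of the 2-fold falls rested on a probe not well above background on any array of the dimmer group, and for 79 of those 136 falls the bound itself reached 2-fold. Among the 1710 tested genes with a symbol, 491 were higher and 610 lower, 80 and 93 of them by at least 2-fold. Of all genes and transcripts tested, 59.3% were called. Counts of called members of a list are to be read beside that share. Higher calls were 45.0% of all calls. They were 49.4% under quantile normalization, 50.7% with median centring and 54.5% with normexp without spots of extreme local background. Without scaling of the arrays, which shifted the median change of all genes by −0.17, they were 22.2%. The excess of lower calls thus depended on the processing. The changes below are relative to each array's 75th percentile.

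Among the 12 largest fitted rises, the log2 change was 5.87 ± 0.03 (SE; adjusted p = 4.66e-08) for PTGS1 and 4.86 ± 0.13 (adjusted p = 2.7e-06) for ABCB1, an efflux transporter. SULF2, an extracellular sulfatase acting on heparan sulfate, changed by 5.57 ± 0.16 (adjusted p = 3.8e-06) and was well above background on 2 of the 3 epidermal arrays. KYNU, an enzyme of tryptophan breakdown, rose by 3.78 ± 0.08 (adjusted p = 1.51e-06), and the protease PRSS23 by 3.23 ± 0.03 (adjusted p = 1.7e-07). TNFRSF11B, the decoy receptor osteoprotegerin, changed by 3.33 ± 0.33 (adjusted p = 0.00042), with 1 of 3 epidermal arrays above background and probes between 1.75 and 3.33. SFRP4, TTR, ANKRD1, TLR2 and SHMT1 rose by 2.99, 2.94, 2.87, 2.76 and 2.70. PRD-SPRRII was not well above background in epidermal cells and was at least 2.02-fold higher in corneal cells (adjusted p = 4.1e-05 for the fitted change). A bound of 2.02-fold is smaller than the measured rise of CRYAB (2.18 on the log2 scale), which was not among the 12. With normexp background correction, as planned, TNFRSF11B and PRD-SPRRII turned to −0.050 and −0.48. SULF2, ABCB1, KYNU, SFRP4, TTR, ANKRD1 and SHMT1 kept their direction in that setting but no longer passed. That setting was distorted by 7 spots of extreme local background on epidermal replicate 1. With those spots left out, TNFRSF11B, PRD-SPRRII and the genes just named rose and passed.

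**Figure D1:**
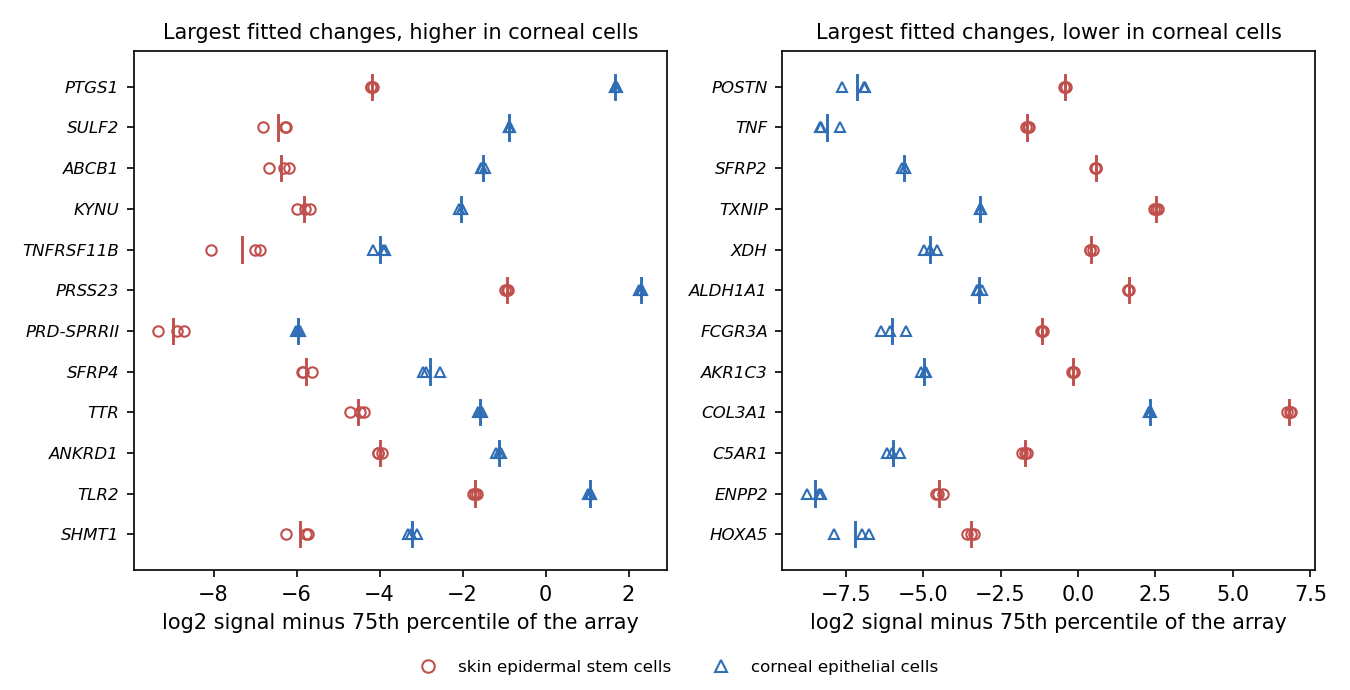
Normalized log2 signal (log2 signal minus the 75th percentile of the array, horizontal axis) on each array for the 12 named genes with the largest fitted rise (left) and the 12 with the largest fitted fall (right). Circles are epidermal and triangles corneal arrays, and vertical bars are group means; PTGS1 means are −4.19 and 1.68, and POSTN means are −0.42 and −7.13, the latter from a probe not well above background. TNFRSF11B and PRD-SPRRII turn direction under the planned normexp correction, which spots of extreme local background distorted, and not with those spots left out.

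Of the 12 largest fitted falls, 4 rested on a probe not well above background in corneal cells and have only a bound. Here and below, the adjusted p beside a bound is that of the fitted change. TNF, the inflammatory cytokine, was at least 25.7-fold lower there (adjusted p = 3.74e-06), and POSTN had an adjusted p of 4.8e-06. SFRP2 fell from 0.57 ± 0.02 to −5.62 ± 0.04 (SD, n = 3), a change of −6.19 ± 0.03 (SE; adjusted p = 4.66e-08). TXNIP, which inhibits thioredoxin and glucose uptake, changed by −5.67 ± 0.04 (adjusted p = 1.02e-07), and XDH, xanthine dehydrogenase, by −5.19 ± 0.11 (adjusted p = 1.33e-06). ALDH1A1, AKR1C3 and COL3A1 changed by −4.83 ± 0.05, −4.81 ± 0.05 and −4.51 ± 0.05. FCGR3A changed by −4.82 ± 0.20 with 1 of 3 corneal arrays above background, and C5AR1 by −4.26 ± 0.11 with 2 of 3. ENPP2 and HOXA5 were at least 3.56-fold and 7.19-fold lower (adjusted p = 7.49e-06 and 0.000189), bounds below the measured 9.25-fold and 9.07-fold falls of ADAMTS1 and MYLK, which were not among the 12. With normexp and spots of extreme local background left out, an alternative chosen after seeing the data, the changes were −3.60 for POSTN, −2.42 for TNF and 2.98 for SULF2. This setting adds an offset of 50, which by construction makes the changes of dim probes smaller.

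Few markers of the corneal surface were measured. Of 3 measured members of the corneal epithelium list, 1 rose and 1 fell, with a mean change of −1.27 and a median of 0.31. PAX6, the master regulator of eye development, rose from −2.66 ± 0.05 to −2.36 ± 0.13 (SD, n = 3). The change was 0.31 ± 0.07 (SE, limma adjusted p = 0.0129). It did not pass without scaling (0.13, adjusted p = 0.237), which shifted the median change of all genes by −0.17. Under the planned normexp correction, which spots of extreme local background distorted, PAX6 turned to −0.26. With those spots left out PAX6 passed as a rise. ALDH1A1, a retinaldehyde dehydrogenase, was the fall. PAX6 was also the single rise among 2 measured eye field transcription factors, and none fell. Of 6 measured limbal progenitor markers, 2 rose and 2 fell. ABCG2, an efflux transporter used as a stem cell marker, rose from −2.14 ± 0.01 to −0.88 ± 0.02 (SD, n = 3), by 1.26 ± 0.03 (SE; adjusted p = 1.46e-06), and SOD2 rose by 0.92 ± 0.03, while TXNIP fell and HGF changed by −0.49 ± 0.04 (adjusted p = 0.000122).

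Basal keratins and TP63 were at or near background in both groups, while PPL and ITGB1 of the keratinocyte lists were bright. Other members of these lists were mostly dim. In epidermal cells DST stood at −4.12, CAV1 at −5.06, CD34 at −5.33 and KRTDAP at −5.77, against −1.91 for SBSN and 0.88 for TCF7L2. KRT5 and KRT14 were well above background on 2 epidermal arrays and 0 corneal arrays, and KRT19 and both TP63 probes on 0 arrays of either group. KRT15 was above background on 3 epidermal arrays and 1 corneal array, with a change of −0.14 ± 0.13 (SE; adjusted p = 0.416). Of 6 measured basal and follicle stem cell markers, 1 rose and 4 fell. Among the falls, CAV1 and DST did not pass without epidermal replicate 2 (limma adjusted p = 0.0598 and 0.0738) or with the added normexp setting. CD34 was not well above background in corneal cells and at least 1.98-fold lower (adjusted p = 0.000769). ITGB1, an integrin subunit on the basal list, changed by 0.15 ± 0.03 (adjusted p = 0.00623) and turned to −0.023 without scaling. Of 3 measured genes of epidermal differentiation, 0 rose and 2 fell, among them PPL, periplakin of the cornified envelope, at −0.54 ± 0.03 (adjusted p = 5.26e-05). The other fall was KRTDAP, which did not pass under quantile normalization (adjusted p = 0.082) and turned to 0.025 with the added normexp setting. Of 8 wound-activated and hair keratins with a probe, 7 were not measured, and the remaining member did not pass over all genes but counted as 1 fall adjusted over the list alone. Of 2 measured simple epithelial markers, 0 rose and 1 fell; that gene, CLDN4, was not well above background in corneal cells and did not pass under quantile normalization (adjusted p = 0.065).

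Epithelial junction genes were split. Of 9 measured members, 3 rose and 3 fell, with a mean change of −0.08, a median of 0.14 and a camera direction upward that did not pass (adjusted p = 0.989). CLDN1, a tight junction claudin, rose by 1.18 ± 0.07 (adjusted p = 6.15e-05), and JUP, plakoglobin of desmosomes, by 0.43 ± 0.04 (adjusted p = 0.000374). MAL2, of apical transport, changed by −1.43 ± 0.05 (adjusted p = 9.86e-06). F11R, a tight junction adhesion molecule, changed by −1.06 ± 0.03 (adjusted p = 3.55e-06), with probes between −1.42 and −0.19.

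VIM, COL1A2 and DCN were bright in both groups. VIM, the mesenchymal intermediate filament, stood at 8.65 ± 0.13 in epidermal and 8.60 ± 0.02 in corneal cells (SD, n = 3), with a change of −0.05 ± 0.07 (SE; adjusted p = 0.558) and probes between −0.050 and 0.0019. COL1A2 stood at 7.22 ± 0.05 and 7.14 ± 0.04, with a change of −0.08 ± 0.04 (adjusted p = 0.118). Without scaling both passed as lower, at −0.22 and −0.25. DCN, decorin, stood at 8.07 ± 0.44 and 8.15 ± 0.03 with a change of 0.07 ± 0.22 (adjusted p = 0.794), which became −0.18 (adjusted p = 0.0115) without epidermal replicate 1. Its other probe stood at 7.91 ± 0.04 and 7.47 ± 0.01 (SD, n = 3), a change of −0.44. Of 22 measured mesenchymal and fibroblast markers, 5 rose and 12 fell, with a mean of −0.93, a median of −0.31 and a median of −0.31 with the dim gene at its bound; the list did not pass camera (adjusted p = 0.181), except with the added normexp setting (0.0375), and passed under fry (4.58e-05). FBLN2, a fibulin of elastic matrix, changed by −2.98 ± 0.12 (adjusted p = 1.42e-05), and COL3A1 and POSTN fell with it. FN1, fibronectin, rose by 0.95 ± 0.03 (adjusted p = 8.01e-06), ASPN by 0.75 ± 0.10 and COL5A2 by 0.74 ± 0.04.

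All 6 measured HOX genes, transcription factors that mark position along the body axis, fell in corneal cells, and the fitted direction of the list was downward under every scaling tried. Their mean change was −1.91 and their median −1.67, or −1.45 and −1.33 with the 3 genes not well above background in corneal cells at their bound. The mean was −1.26 under the planned normexp correction and −0.72 with the added one. HOXA7 fell from −0.55 ± 0.01 to −2.25 ± 0.01 (SD, n = 3), a change of −1.71 ± 0.03 (SE; adjusted p = 4.75e-07), and HOXC13 was at least 1.85-fold lower (adjusted p = 0.00521). Taken singly, 2 of the 6 passed under the planned normexp correction and 4 of the 6 with the added one. The list passed camera with the preset correlation (adjusted p = 0.0178). Its adjusted p was 0.737 with an estimated correlation and 0.0529 without genes named from descriptions or older names, so the call ended there. The estimated correlation of the HOX genes was negative (−0.17). The list's unadjusted camera p still rose from 0.00127 to 0.0298, since that variant uses only the residual degrees of freedom of the 6 arrays. The loss of the call therefore does not show that correlation among these genes had made the call.

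**Figure D2:**
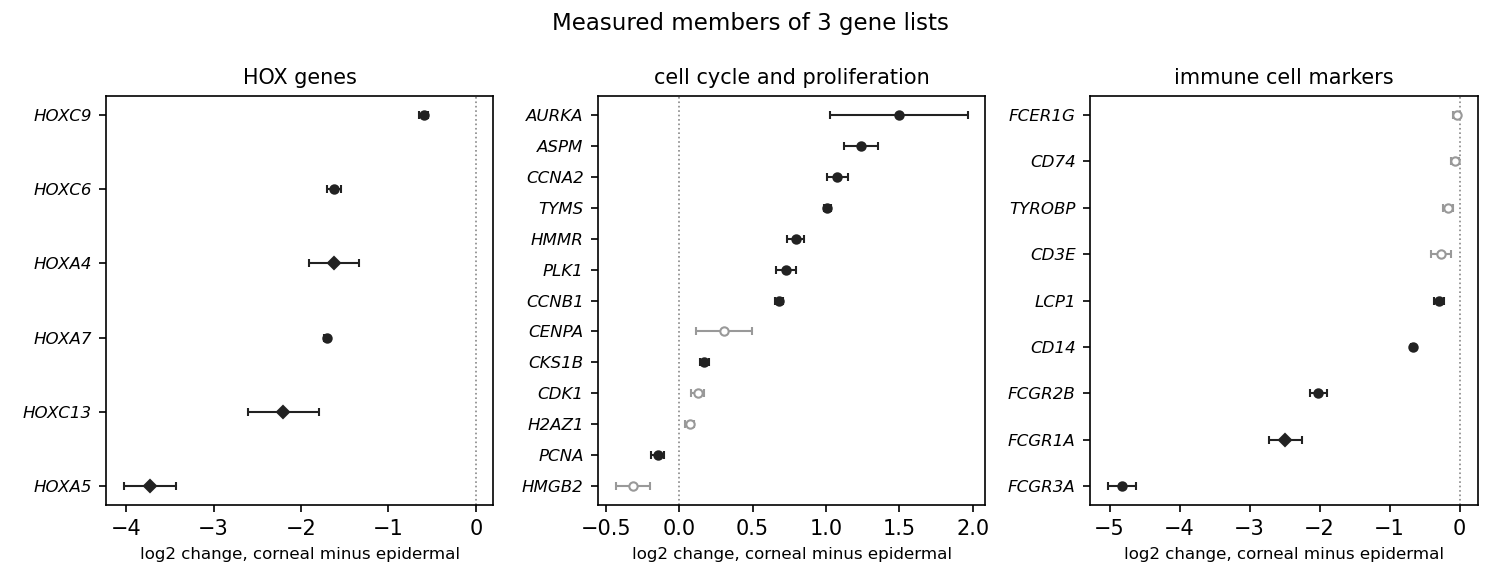
Log2 change, corneal minus epidermal (horizontal axis), of each measured member of the HOX, cell cycle and immune cell lists, with bars of 1 SE from limma. Filled marks passed an adjusted p of 0.05, open grey marks did not, and diamonds are fitted values of genes not well above background in corneal cells, which are not bounds; all 6 HOX marks lie below 0, with HOXA5 at −3.73.

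Markers of other cell types moved in both directions. Of 9 measured immune cell markers, 0 rose and 5 fell, with a mean of −1.20 and a median of −0.29 that was the same with the dim gene at its bound, and the list did not pass camera (adjusted p = 0.0611) except without corneal replicate 1 (0.0468), and passed under fry (6.78e-06). The Fc receptors FCGR3A and FCGR2B fell, the latter by 2.02 on the log2 scale (SE 0.12), and FCGR1A was at least 1.60-fold lower, a call that ended with the added normexp setting (adjusted p = 0.0614). CD14 changed from 4.50 ± 0.03 to 3.84 ± 0.02, and TYROBP, with −0.16 ± 0.07, did not pass (adjusted p = 0.113) but passed without scaling at −0.33. Of 6 measured endothelial markers, 0 rose and 4 fell, with a mean of −0.47, or −0.18 with dim genes at their bound. FLT1 was among the falls at −0.63 ± 0.08 (adjusted p = 0.000935). Its call, and those of TIE1 and VWF, ended with the added normexp setting. ENG and EGFL7, the brightest of the 6, had changes of 0.20 ± 0.11 and 0.25 ± 0.11 that did not pass, though EGFL7 did without epidermal replicate 2 (0.37). Of 8 measured corneal stroma markers, 3 rose and 2 fell, with a mean of −0.02, a median of −0.06 and an upward camera direction; with dim genes at their bound the mean was 0.18 and the median −0.02. BGN, a small proteoglycan, rose by 1.32 ± 0.06 (adjusted p = 1.6e-05) and CHI3L1 by 1.19 ± 0.05 (adjusted p = 1.5e-05), while LUM, lumican, changed by −0.39 ± 0.04 from a level of 4.83 ± 0.06. Of 5 measured corneal endothelium markers, 2 rose and 0 fell, or 1 rose adjusted over the list alone; ATP1B1, a sodium pump subunit, rose by 0.82 ± 0.03.

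The 4 measured smooth muscle and pericyte markers gave 3 rises and 1 fall, with a mean of −0.10 and a median of 0.78. MYLK, myosin light chain kinase, changed by −3.18 ± 0.10 (adjusted p = 6.15e-06), while CNN1, calponin, rose by 1.08 ± 0.04 and TPM1 by 0.47 ± 0.03. Neural crest and Schwann cell markers gave 2 rises and 1 fall among 5 measured, with TFAP2A, a transcription factor also of surface ectoderm, at 1.24 ± 0.07 (adjusted p = 5.02e-05). MBP, at 0.24 ± 0.03, did not pass without scaling (adjusted p = 0.47), and PMP22 changed by −0.14 ± 0.03. Skeletal muscle markers gave 1 rise and 1 fall among 5 measured, with a mean of 0.06, a median of −0.20 and a downward camera direction. DES, desmin, was the rise at 1.21 ± 0.09, and MYL11 had a change of −0.04 ± 0.09. The planned normexp correction, which spots of extreme local background distorted, turned DES to −0.19. With those spots left out DES passed as a rise. Of 6 measured adipocyte markers, 1 rose and 3 fell. PPARG, the adipogenic nuclear receptor, was at least 5.49-fold lower in corneal cells (adjusted p = 0.000104), LEP rose by 1.44 ± 0.09, and PLIN1 had a change of −0.06 ± 0.06 that passed without scaling at −0.23. The 1 measured melanocyte marker, EDNRB, had a change of 0.22 ± 0.08, with probes between −0.20 and 0.22, that did not pass over all genes (adjusted p = 0.0672) and passed adjusted over the list alone, as 1 rise, and over all genes under quantile normalization (0.25). Of 2 measured pluripotency factors, 0 rose and 1 fell, MYC at −0.51 ± 0.05 (adjusted p = 0.000339).

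Of 13 measured cell cycle genes, 8 rose and 1 fell, or 9 and 2 adjusted over the list alone, with a mean change of 0.56 and a median of 0.68. The mean was 0.12 under the planned normexp correction and 0.41 with the added one. CCNA2, cyclin A2, rose from −3.03 ± 0.08 to −1.95 ± 0.11 (SD, n = 3), by 1.08 ± 0.07 (SE; adjusted p = 7.94e-05), and ASPM, a spindle pole protein, by 1.24 ± 0.12 (adjusted p = 0.000335). The list passed camera with the preset correlation (adjusted p = 0.0178). Its adjusted p was 0.808 with an estimated correlation and 0.239 without genes named from descriptions or older names, so the call ended there. Of 11 measured cell cycle inhibitors and senescence genes, 2 rose and 8 fell (camera adjusted p = 0.181). CDKN1C, the inhibitor p57, changed by −1.75 ± 0.04 (adjusted p = 2.29e-06), and IGFBP5 by −1.85 ± 0.05 (adjusted p = 2.96e-06).

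Of the signalling lists, those of Wnt, of TGF-beta and BMP and of growth factors did not pass camera, and that of Notch had too few measured members to be tested. Of 8 measured Wnt genes, 3 rose and 5 fell; beside SFRP2 and SFRP4, the receptor FZD2 rose by 0.94 ± 0.04, FZD7 changed by −0.86 ± 0.04 and CTNNB1, beta-catenin, rose by 0.40 ± 0.05. Of 4 measured Notch genes, 0 rose and 2 fell, the ligand JAG1 at −1.92 ± 0.07 (adjusted p = 7.58e-06) and ADAM17 at −0.62 ± 0.03. Of 21 measured TGF-beta and BMP genes, 5 rose and 9 fell. BMP4 rose from −1.53 ± 0.00 to 0.02 ± 0.03 (SD, n = 3; adjusted p = 1.1e-06), while FST, follistatin, changed by −1.61 ± 0.04, LTBP1 by −1.28 ± 0.04 and TGFB1 by −0.83 ± 0.04. Of 24 measured growth factor and receptor genes, 11 rose and 9 fell, or 11 and 10 adjusted over the list alone; the median was 0.24 and fry's direction was downward while camera's was upward. IGF2 changed by −2.56 ± 0.07 (adjusted p = 2.62e-06) and FGFBP1 by −1.23 ± 0.09, whereas the binding proteins IGFBP2 and IGFBP4 rose by 1.54 ± 0.08 and 1.02 ± 0.03.

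Matrix genes were also mixed. Of 7 measured basement membrane genes, 3 rose and 3 fell. BCAM, a laminin receptor, rose by 1.94 ± 0.05 (adjusted p = 2.97e-06), and LAMA4, a laminin chain, changed by −1.02 ± 0.04 (adjusted p = 1.05e-05). COL4A2, at 0.14 ± 0.04 with probes between −0.15 and 0.14, turned to −0.028 without scaling. Of 15 measured matrix proteases and inhibitors, 6 rose and 7 fell, with a mean of −0.01, a median of −0.05 and an upward camera direction. MMP1, interstitial collagenase, rose by 1.86 ± 0.04 (adjusted p = 1.1e-06), and TIMP3 by 1.26 ± 0.03 (adjusted p = 1.98e-06) with probes between 0.01 and 1.26. ADAMTS1, a proteoglycan-cleaving protease, changed from 4.37 ± 0.02 to 1.16 ± 0.05 (SD, n = 3; adjusted p = 1.7e-07), and CTSK by −0.72 ± 0.05.

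Interferon and inflammatory lists held changes in both directions. Of 10 measured interferon response and antigen presentation genes, 4 rose and 4 fell, or 4 and 5 adjusted over the list alone, with a mean of 0.14, a median of −0.09 and an upward camera direction that did not pass (adjusted p = 0.987). The interferon-induced MX2, MX1 and ISG15 rose by 1.66 ± 0.05, 1.27 ± 0.03 and 1.15 ± 0.03, while the antigen processing genes PSMB9, TAP1 and TAP2 changed by −1.23 ± 0.04, −0.63 ± 0.12 and −0.47 ± 0.05. Of 17 measured inflammatory genes, 7 rose and 8 fell, or 7 and 9 adjusted over the list alone, with a mean of −0.18, or −0.07 with the dim gene at its bound, a median of −0.10 and an upward camera direction (adjusted p = 0.987). PTGS2, the inducible cyclooxygenase, rose from 3.09 ± 0.02 to 4.63 ± 0.03 (SD, n = 3; adjusted p = 1.1e-06), and TLR2 rose with it, while IL1A and IL18 changed by −1.56 ± 0.05 and −1.23 ± 0.04. Of 16 measured crystallins, antioxidants and aldehyde enzymes, 6 rose and 9 fell. CRYAB, a small heat shock protein also found in lens, rose by 2.18 ± 0.04 (adjusted p = 9.89e-07), and GPX3 and GSTM3, of peroxide and glutathione metabolism, changed by −2.17 ± 0.04 and −1.90 ± 0.04.

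Of 12 measured glycolysis and hypoxia genes, 8 rose and 3 fell, with a mean of 0.40, and the list did not pass camera (adjusted p = 0.0611) except without scaling (0.0136), under the planned normexp correction (0.000587) and without corneal replicate 1 (0.0468). It passed under fry (adjusted p = 4.58e-05). The glucose transporters SLC2A3 and SLC2A1 rose by 1.54 ± 0.03 and 1.10 ± 0.04 (adjusted p = 1.74e-06 and 1.28e-05), and EPAS1 by 0.98 ± 0.09, while DDIT4 changed by −0.87 ± 0.08.

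Under the normexp correction as planned, which one epidermal array with 7 spots of extreme local background distorted, 178 genes were higher and 201 lower, and 109 of the 156 named genes that had passed no longer did, 14 of them with the direction turned. With those spots left out the counts were 3633 and 3031, and 215 and 188 by at least 2-fold. Under fry, which does not compare a list with other genes, 20 lists passed that did not with camera.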

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

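The alternatives were chosen before the data were examined, except 3 tests chosen after the result was seen: outlier spots kept, names from descriptions or older names not used, and normexp without spots of extreme local background. Of 167 named genes, 117 changed their side of the threshold or direction under at least 1 setting, 109 of them under normexp as planned, where all 109 no longer passed. Of 28 tested lists, 22 did so, 20 of them by passing under fry but not with camera, 1 of these, the epithelial junction list, in the other direction. The signal over background limits dim probes. Requiring all 6 arrays above background left 332 genes higher and 255 lower by at least 2-fold, by construction without genes at background in either group.

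Normexp as planned left 178 genes higher and 201 lower, 110 and 146 of them by at least 2-fold, and 2 lists higher. On epidermal replicate 1, 7 spots had a local background over 10 times the median of 46, up to 23844, and the fitted background mean was −888 there; without them it was 1.44, and the 2-fold counts were 215 higher and 188 lower with 3 lists lower. Without scaling, 1419 genes and 2 lists were higher. Testing against a 2-fold change with treat, which is stricter by construction, gave 222 higher and 266 lower. Leaving out arrays gave 1 to 2 lists higher and 1 to 2 lower. Glycolysis and immune cells were the additions without corneal replicate 1, and ribosomal proteins without epidermal replicate 1. With an estimated correlation, 0 lists passed camera in either direction, and 1 list, that of HOX genes, had an unadjusted p under 0.05 (0.0298). Without names from descriptions or older names, 0 lists passed in either direction, with fewer members measured. The HOX list had 3 members with the filter on all 6 arrays, too few to test, so 0 lists were lower. Under fry, 8 lists were higher and 14 lower. With camera, adjusted p ran from 0.00459 to 0.737 for HOX genes and from 0.00459 to 0.808 for the cell cycle over the settings tried, and under fry it was 1.22e-07 and 8.06e-05.

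Under normexp as planned, direction turned for TNFRSF11B (−0.050), PRD-SPRRII (−0.48), PAX6 (−0.26), ESRP2 (−0.66), DES (−0.19), TGFBR1 (−0.0084), FGF18 (−0.67), HSPG2 (−0.26), MMP13 (−0.47), CSF3 (−0.59), MGST1 (−0.14), DNAJB4 (−0.20), ATP5PO (0.027) and SDHD (0.0099); this setting shifted the median change of all genes by −0.25. Without scaling, ITGB1 (−0.023), COL4A2 (−0.028) and ATP5F1B (−0.034) turned, with the shift of −0.17. With normexp without spots of extreme local background, KRTDAP (0.025), CLDN4 (0.079), VWF (0.050), MYOG (0.12) and RPS15 (0.067) turned. DCN ranged from −0.18 to 0.21 with arrays left out, and the epithelial junction list, with a mean of −0.078, had an upward direction in camera and a downward one under fry, which does not compare a list with other genes. Beyond what is stated, the cause was not tested.

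The replicate numbers were also fitted as a replicate block, with 2621 genes higher and 3250 lower, 371 and 430 by at least 2-fold, and 1 list in each direction. The deviations of same-numbered arrays correlated at 0.02, −0.02 and 0.04, and those of differently numbered arrays at −0.05 to 0.03. The deviations were as small as the spread between spots of an array. These correlations therefore cannot tell whether same-numbered samples share an origin. A slide or scan block was not run, since there was 1 slide and 1 scan.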

Other observations

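The tests of macrophage transcripts, of keratin markers, of probe detection and of HOX genes at their bound were chosen after the result was seen.

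Of 38 measured cytosolic ribosomal protein genes, 4 rose and 15 fell, or 4 and 13 adjusted over the list alone, with a mean of −0.14 (camera adjusted p = 0.194) that turned to 0.028 under normexp as planned. The list passed as lower with normexp without spots of extreme local background (0.0375), without epidermal replicate 1 (0.0407) and under fry (0.00888). RPL22 changed by −1.02 ± 0.03 (SE; adjusted p = 2.94e-06). Of 14 measured oxidative phosphorylation genes, 1 rose and 3 fell, with a mean of −0.01 and a median of 0.02, and ATP5PF changed by −0.22 ± 0.04 (adjusted p = 0.00704). Of 12 measured cholesterol and fatty acid genes, 1 rose and 4 fell, or 1 and 2 adjusted over the list alone, with a mean of 0.05, a median of −0.04 and a downward camera direction.

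Of 14 measured protein folding and stress genes, 3 rose and 6 fell, or 4 and 6 adjusted over the list alone, with CALR, calreticulin, at −0.65 ± 0.03 (adjusted p = 3.29e-05) and DNAJA1, a heat shock co-chaperone, at 0.49 ± 0.03 (adjusted p = 7.07e-05). Of 10 measured immediate early genes, 4 rose and 4 fell. CCN2, a matricellular growth factor, rose from 2.76 ± 0.05 to 4.79 ± 0.02 (SD, n = 3; adjusted p = 7.47e-07), and CCN1 and ANKRD1 rose too. EGR1 changed by −1.95 ± 0.07 (adjusted p = 1.07e-05), with probes between −1.95 and −0.21, and FOS by −0.98 ± 0.04. Of 4 measured retinoid genes, 1 rose and 2 fell, or 1 and 3 adjusted over the list alone; DHRS3, a retinaldehyde reductase, rose by 1.97 ± 0.05 (adjusted p = 3.04e-06), and TGM2 changed by −1.41 ± 0.09.

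All 6 HOX genes measured fell in corneal cells. A shift that depends on probe brightness is argued against: 0.03% of 10000 random lists of other genes matched on mean level had a mean as low as −1.91, the matched median being −0.15 with the central 95% between −0.95 and 0.42. With genes at background set to their bound, 0.07% of lists were as low as −1.45. Slide row is confounded with cell type and stays open, as does the body region from which the cells came, which may set HOX levels and was not tested.

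FCGR3A, C5AR1 and TNF fell together in corneal cells, and macrophages in the epidermal cultures are a candidate source. FCER1G and CD74 were chosen after their values were seen, with TYROBP, as general macrophage transcripts; the largest fall among the 3 was −0.16, and CD14 fell by 0.66. Among myeloid genes that missed the detection filter, ITGB2, NCF1 and LYZ were well above background on up to 2 epidermal and 0 corneal arrays, CYBB on 0 and up to 1, and ITGAM and CD4 on 0 of either, too near background to decide. TYROBP, FCER1G and CD74 were well above background on the corneal arrays too, and this baseline could hide a small share of such cells, so macrophage RNA and a difference between the cells themselves cannot be told apart.

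KRT5, KRT14, KRT19 and TP63 missed the detection filter while VIM, COL1A2 and DCN were bright in both groups. Of KRT5, KRT14, KRT15, KRT19 and TP63, 1 was well above background on at least 3 arrays, which restates the pattern. Otherwise epithelial cultures would keep bright basal keratins, so a small share of fibroblasts could account for the pattern only if the keratin probes failed too. VIM, DCN and COL1A2 (8.65, 8.07 and 7.22 in epidermal, 8.60, 8.15 and 7.14 in corneal cells) stood near GAPDH (7.79 and 8.16). These levels argue against a small share, as far as different probes can be compared. A failure of probes whatever their gene stays open. Without KRT5, KRT14, KRT19, TP63 and the wound-activated and hair keratins, 17.9% of 28 epithelial list genes with a probe were not measured, against 14.1% of 1963 others (Fisher's exact test, two-sided, p = 0.582). With them it was 40% of 40 genes (Fisher's exact test, p = 6.65e-05), a value that rests on genes chosen for the pattern and on hair keratins. All 22 mesenchymal genes with a probe were measured. COL1A1 (7.10 in epidermal, 6.55 in corneal cells) and SPARC (7.16 and 6.88) were bright too, while others such as TNC (−1.86 and −4.16) were dim. Failure of the keratin probes alone would not account for the bright mesenchymal transcripts. Whether those probes failed, and whether the cultures are largely mesenchymal or have lost epithelial features, stays open and was not tested.

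Among the 10 splits of the 6 arrays into 3 and 3, the real split gave 2960 genes higher and 3617 lower and 373 and 437 by at least 2-fold, and the highest other split gave 0 with limma, where up to 160 genes had an unadjusted p under 0.05, against 7065 in the real split. The real split was the 1 split with counts as large. For lists, the real split gave 1 higher and 1 lower, and the highest other gave 1, so that 5 of 10 splits gave as many. With 10 splits, no share under 0.05 can be reached. Every other split also mixed the 2 kinds of cells, whose difference then widened the spread within its groups. The 0 calls there therefore say little about chance.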
